A study of Mus musculus with 36 samples.

How the data were processed

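Libraries of total RNA were made with the KAPA kit, per the submitters' notes, from liver and quadriceps of male C57BL6/J mice, 3 sham and 5 at each of days 1, 3 and 7 after PHx. Per those notes, the authors used FastQC 0.11.5, STAR 2.7.10a, featureCounts (own version not given), Subread 2.0.3 and edgeR 3.40.2 on mouse genome build mm10. The deposited table gives read counts per gene, unnormalized, for 36 libraries, and beside them the log2 fold changes the authors obtained for each PHx day against sham and the deposited FDR, an adjusted p-value. Their model, test and normalization are not stated. A further 36 columns of per-sample values were not used. The table holds 14702 genes, of which 2 symbols are duplicated and 23 are written as dates, and these were kept as they stand. Every gene exceeded 0.5 CPM in at least 4 libraries. The table has 0 mitochondrial genes. Symbols of 683 genes had no match in the RefSeq annotation.

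Groups followed the sample titles. Within each tissue 18 libraries entered a single fit in R 4.3.3 with edgeR 4.0.16: filterByExpr on the groups (13879 liver and 13601 quadriceps genes stayed), TMM scaling, estimateDisp, glmQLFit with robust set, and two-sided quasi-likelihood F-tests for each day against sham, for day 1 to day 3 and for day 3 to day 7. Benjamini-Hochberg adjustment ran over all genes of a comparison, at 0.05. Genes that responded differently by tissue were tested by the interaction term over 36 libraries and the 12780 genes that passed in both tissues, with TMM within tissue. Lists of genes, written from general knowledge, were tested for each day against sham by camera (limma 3.58.1, preset correlation 0.01), adjusted over lists and days within a tissue, and list members were also adjusted over the list alone. Of 40 liver and 32 quadriceps lists, 38 and 31 held enough genes. Overlaps between tissues were tested by two-sided Fisher's exact test against genes tested in both.

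The comparisons, lists, naming rule and most of the other settings were fixed before the data were examined. The rule named, first, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM whose PHx libraries all lay beyond all sham libraries, leaving out predicted gene models (4 and 4 between days and between tissues). Next it named up to 4 members with the smallest p in each list discussed, and then fixed genes of growth, liver function and muscle wasting, called or not. Some genes that these rules name are not reported here. The other settings fixed then were size factors as in DESeq2, no filter, DESeq2 1.42.0, the compared groups alone, a block for replicate number, leaving out each library in turn, fry and an estimated correlation for lists, and TMM over all libraries for the interaction. Settings added after seeing the data were a likelihood ratio test, an adipocyte covariate, the day 1 libraries rich in muscle or islet reads alone, and leaving out 401 genes open to muscle reads in liver. Main tests did not take replicate numbers to mean the same animal in both tissues. Splits of the tissue difference did.

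Tests were tried on data simulated from the same libraries, with 67, 67 and 66 genes per tissue changed 1.5-, 2- and 4-fold. In liver at day 3 edgeR found 4.48%, 37.3% and 84.8%, and in quadriceps 1.49%, 19.4% and 74.2%. False calls were 1.18% and 2.94% of calls. The interaction test found 13.3% of 2-fold differences. The authors' deposited FDR called 4140, 4524 and 3330 genes in liver and 2118, 6837 and 300 in quadriceps at days 1, 3 and 7, of which 3367, 3551, 2351, 673, 6042 and 8 were also called here, 0 with the opposite sign. The data have far more calls than the simulation had changes, so its rates may differ. For genes called against sham or between days with 0 to 3 reads in a group, a floor of 3 counts over the group or an exact 95% counting interval is given, and for such genes in the tissue comparison the adjusted p. Floors and intervals cover counting error only, since PCR copies are not separate molecules.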

Results

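Total RNA was sequenced from liver and quadriceps muscle of adult male C57BL6/J mice after surgical removal of 70% of the liver (partial hepatectomy, PHx), after which the remaining lobes grow back. The title of the series ties hepatic Yap1, a transcriptional co-activator that drives growth, to catabolism in the whole body and to loss of muscle. The comparisons ask what PHx changed in the liver and in a distant muscle. Each tissue had 4 groups: 3 libraries from sham mice, whose abdomen was opened without resection, and 5 libraries each from days 1, 3 and 7 after PHx, 36 libraries in all. Days come from the sample titles. The treatment field named day 3 for every sample, sham included, and the day of the sham samples is unknown. Total counts ran from 12464547 to 28862458 per liver library and from 15506197 to 29623890 per quadriceps library. Changes are log2 fold changes ± SE, of 5 PHx against 3 sham libraries, and expression is mean CPM, counts scaled to library size, ± SD over the same libraries. A gene "rose" or "fell" where edgeR gave an adjusted p under 0.05. A list's adjusted p, printed after its last gene, is camera's. camera called 65 liver and 55 quadriceps lists at its preset correlation and 0 at an estimated one.

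The first comparison asked what had changed in the remaining liver 1 day after PHx. Stress and acute phase genes were among those that rose most. Large rises were seen in Fosl1, an AP-1 transcription factor (8.15 ± 2.23), Sult1e1, an oestrogen sulfotransferase (7.48 ± 1.84), Saa2, an acute phase apolipoprotein (7.15 ± 1.38), and Slc34a2, a phosphate transporter (7.13 ± 1.17). Sphk1, which makes sphingosine 1-phosphate, also rose, with 549 reads over the day 1 libraries and 3 over the sham libraries, a ratio of 132 (95% exact counting interval 44.9 to 641). The largest falls were the clock output gene Dbp (-4.36 ± 0.84), Nrep (-4.10 ± 0.99), Keg1 (-4.0 ± 1.05), the steroid dehydrogenase Hsd3b5 (-3.60 ± 0.98), Tnfsf10, the death ligand TRAIL (-3.59 ± 0.65), and the uridine phosphorylase Upp2 (-3.54 ± 1.20). Slc34a2 was 7.87 without sham replicate 1, Fosl1 8.89 and Sult1e1 8.09 without sham replicate 2 and Nrep -4.83, Keg1 -4.89 and Tnfsf10 -4.26 without day 1 replicate 1. Slc34a2 was 6.35 without day 1 replicate 2 and Fosl1 7.42, Sult1e1 6.32, Dbp -5.01 and Upp2 -4.70 without day 1 replicate 5. Fosl1 was not called without any 1 sham, nor Upp2 without any 1 sham or day 1 replicate 1, 2, 3 or 4 (edgeR, adjusted p 0.0515 to 0.0818). Sphk1 was at least 83.9-fold higher without sham replicate 1, 86.5-fold higher without sham replicate 3 and 82.98-fold higher without day 1 replicate 5.

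Of the acute phase proteins, 21 of 30 (adjusted over the list alone, 23) rose and 1 fell, with Lrg1 (2.33 ± 0.35) and Serpina3n (3.17 ± 0.55) among them (adjusted p = 8.75e-11). Lcn2, a siderophore-binding protein of inflammation, rose by 6.02 ± 1.02, from 37.9 ± 24.7 to 2458 ± 1681 CPM. Genes of JAK-STAT3 and NF-kB signalling rose in 13 of 31 (adjusted over the list alone, 18), such as Cebpd (3.23 ± 0.54), while the interferon regulator Irf1 fell (-1.95 ± 0.28; adjusted p = 6.01e-05). Neutrophil markers rose in 8 of 9 (adjusted over the list alone, 8), including S100a8 (4.04 ± 1.0; adjusted p = 0.000627). Glucocorticoid receptor targets rose in 14 of 26 (adjusted over the list alone, 19), among them the mTORC1 inhibitor Ddit4 (3.98 ± 0.67; adjusted p = 8.37e-07). Of the p53 targets, 9 of 23 (adjusted over the list alone, 9) rose, led by the cell cycle inhibitor Cdkn1a (6.99 ± 0.92) with Btg2 (3.97 ± 0.74) and the stress hormone Gdf15 (4.19 ± 0.85; adjusted p = 0.00285). Ribosome biogenesis genes rose in 25 of 35 (adjusted over the list alone, 29), such as Rrp12 (1.88 ± 0.32) and the polyamine enzyme Odc1 (2.40 ± 0.50; adjusted p = 4.63e-10). The unfolded protein and integrated stress response rose in 14 of 32 (adjusted over the list alone, 14), with the chaperone Hspa5 (1.61 ± 0.30) and Atf3 (4.65 ± 0.99; adjusted p = 0.00027). S100a8 was 2.83, Btg2 3.13, Gdf15 3.57 and Atf3 3.73 without day 1 replicate 5.

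Matrix genes rose in 10 of 35 (adjusted over the list alone, 16), among them the basement membrane collagens Col4a1 (2.46 ± 0.23) and Col4a2 (1.52 ± 0.17; adjusted p = 3.71e-05). Of a list of humoral factors discussed in muscle wasting, which also holds the TWEAK receptor, 13 of 33 (adjusted over the list alone, 17) rose, including that receptor, Tnfrsf12a (4.72 ± 0.81), and the activin subunit Inhbb (3.80 ± 0.67; adjusted p = 0.000442). Lipid synthesis went the other way. Cholesterol synthesis genes fell in 19 of 25 (adjusted over the list alone, 21), such as Sc5d (-2.77 ± 0.40) and Idi1 (-2.06 ± 0.31; adjusted p = 2.29e-16). Fatty acid synthesis genes fell in 13 of 23 (adjusted over the list alone, 14), such as Acaca (-1.42 ± 0.20) and Elovl6 (-2.40 ± 0.34; adjusted p = 1.29e-07). Interferon response genes fell in 6 of 33 (adjusted over the list alone, 6) and rose in 3, with Irf9 (-1.32 ± 0.31) and Gbp7 (-1.63 ± 0.50) lower (adjusted p = 0.00195). Inhbb was 4.46 without sham replicate 1. Gbp7 was not called without any 1 sham (edgeR, adjusted p 0.0601 to 0.0784).

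Proliferation genes had not risen as a group at day 1. edgeR called 0 of 48 S phase genes higher (5 at an unadjusted p under 0.05, DESeq2 4) and 4 lower (adjusted over the list alone, 3), among them Mcm10 (-2.65 ± 0.58) and Tk1 (-2.66 ± 0.69), with a median of -0.04, a mean of 0.20 and no camera call (adjusted p = 0.733). The proliferation marker Mki67 stood at 8.86 ± 7.33 CPM against 9.56 ± 1.63 in sham (-0.11, adjusted p = 0.938). Igfbp1, which binds insulin-like growth factors, rose by 4.22 ± 1.02, and the YAP-related genes Wwtr1 (0.66 ± 0.18), Ctgf (2.64 ± 0.57) and Ankrd1 (3.13 ± 0.86) rose. Not called were Yap1 (0.14, adjusted p = 0.576), Cyr61 (2.20, 0.058), Ccnd1 (0.89, 0.27) and Afp (1.59, 0.0565). Nor were Alb (-0.04, 0.939), Cyp7a1 (-4.30, 0.0611), Hnf4a (-0.00041, 0.999), Igf1 (-0.14, 0.697), Fgf21 (3.44, 0.0746) and Inhba (-0.99, 0.292). Wwtr1 and Ankrd1 were not called without sham replicate 1 or 2 (edgeR, adjusted p 0.0544 to 0.071). Cyp7a1 was -5.28 and Inhba -2.07 without day 1 replicate 1. Cyr61 was called without day 1 replicate 1 or 3 and Cyp7a1 and Inhba without day 1 replicate 1 (edgeR, adjusted p 0.00838 to 0.0353).

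In all, 3841 of 13879 genes passed at day 1, 2319 higher and 1522 lower, of which 1350 and 795 changed at least 2-fold. Muscle fibre transcripts averaged 288 ± 81.1 CPM in the sham livers and 205 ± 274 CPM at day 1, where replicates 1 and 2 held 355 and 621 CPM. The count was 1923, 1935 or 1797 without sham replicate 1, 2 or 3, and 1307 with only these 2 groups in the fit. It was 2003 with day 1 replicates 1 and 2 alone, a setting chosen after seeing the data.

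By day 3, the time of hepatocyte division in the regrowing mouse liver, the question was which programmes had risen or fallen against sham. Cell cycle, matrix and fetal genes rose, and male-biased, P450 and pericentral genes fell. Lcn2 rose by 7.50 ± 1.10, to 6881 ± 3427 CPM. Afp, the fetal counterpart of albumin, rose by 5.98 ± 0.69, from 0.772 ± 0.245 to 48.6 ± 22.97 CPM, and Mki67 by 3.60 ± 0.98, from 9.56 ± 1.63 to 116 ± 38.2 CPM. The largest falls were Hsd3b5 (-7.25 ± 1.14), the sulfotransferase Sult2a8 (-6.78 ± 1.49), the adipocyte marker Cfd (-6.29 ± 1.18), the organic anion transporter Slco1a1 (-6.21 ± 1.22), the carbonic anhydrase Car3 (-6.00 ± 1.79) and the methyltransferase Inmt (-5.88 ± 1.49). Sham replicate 2 held 35.9 CPM of Cfd, against 1.14 and 2.48. Cfd was -3.44 without sham replicate 2, Hsd3b5 -8.77, Sult2a8 -8.03, Slco1a1 -7.85, Car3 -7.89 and Inmt -7.45 without day 3 replicate 1 and Cfd -7.18 without day 3 replicate 2. Mki67 was not called without sham replicate 1 (edgeR, adjusted p = 0.0563).

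Transcripts of pancreatic islet hormones took 3 of the 6 largest rises. Ins2 (insulin) had 4867 reads, Gcg (glucagon) 2149 and Iapp (amylin) 1207 over the day 3 livers, and each had 0 over the sham livers: they were at least 1168-fold, 516-fold and 289.6-fold higher, against a floor of 3 counts over the sham group. All 5 day 3 livers held Ins2 reads (73 to 2493). The granin Scg2, also made in endocrine cells, rose with 1060 reads against 3, a ratio of 254 (95% exact counting interval 86.8 to 1235). Ypel4 rose with 901 reads against 2, a ratio of 324 (89.5 to 2682). Gcg was at least 328-fold, Iapp at least 184-fold, Ins2 at least 743-fold and Ypel4 at least 138-fold without sham replicate 1. Gcg was at least 338-fold, Iapp at least 189.9-fold, Ins2 at least 766-fold, Scg2 500.4-fold and Ypel4 213-fold without sham replicate 3. Gcg was at least 333-fold, Iapp at least 181-fold, Ins2 at least 741-fold and Scg2 166-fold without day 3 replicate 3.

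Mitosis genes rose in 45 of 46 (adjusted over the list alone, 45), such as Mad2l1 (2.61 ± 0.44), Plk4 (3.11 ± 0.56) and Cep55 (3.56 ± 0.70), with the securin Pttg1 lower (-0.91 ± 0.16; adjusted p = 2.14e-15). S phase genes rose in 35 of 48 (adjusted over the list alone, 36), among them Ccne1 (2.79 ± 0.58) and the helicase subunit Mcm3 (3.20 ± 0.67; adjusted p = 1.21e-09). Fetal and progenitor genes rose in 9 of 16 (adjusted over the list alone, 10), including Cd24a (4.05 ± 0.49) and Igf2bp3 (4.44 ± 0.88; adjusted p = 1.18e-05). Of the acute phase proteins 24 of 30 (adjusted over the list alone, 25) rose, such as Orm2 (5.80 ± 0.81; adjusted p = 4.78e-12). Matrix genes rose in 28 of 35 (adjusted over the list alone, 31), with Col4a1 (2.48 ± 0.23) and the crosslinking enzyme Loxl2 (2.97 ± 0.44; adjusted p = 1.37e-15). Stellate cell and fibroblast markers rose in 8 of 18 (adjusted over the list alone, 8), among them Col1a1 (3.91 ± 0.79) and Acta2 (3.54 ± 0.77; adjusted p = 0.0361). Neutrophil markers rose in 8 of 9 (adjusted over the list alone, 8) (Mmp8, 5.37 ± 1.10; adjusted p = 0.000109). Macrophage and monocyte markers rose in 8 of 19 (adjusted over the list alone, 11) (Trem2, 3.96 ± 0.90; adjusted p = 0.000566). The humoral factor list rose in 15 of 33 (adjusted over the list alone, 15) and fell in 3, with Inhbb (3.56 ± 0.66) and the growth factor Hgf (1.34 ± 0.22) higher (adjusted p = 0.00155). Inhbb was 4.23 without sham replicate 1 and Mmp8 5.98 without sham replicate 2.

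Growth hormone dependent, male-biased genes fell in 18 of 25 (adjusted over the list alone, 23), such as Cyp7b1 (-3.56 ± 0.46) and the growth hormone receptor Ghr (-2.53 ± 0.45; adjusted p = 1.91e-12). Drug and steroid P450 genes fell in 16 of 26 (adjusted over the list alone, 16), including Cyp2c54 (-5.33 ± 0.66) and Cyp2c37 (-4.04 ± 0.56; adjusted p = 1.55e-08). Pericentral hepatocyte genes fell in 12 of 20 (adjusted over the list alone, 14), such as Rgn (-3.88 ± 0.63) and Cyp2e1 (-2.70 ± 0.48; adjusted p = 1.29e-07). Mature hepatocyte markers went both ways, 6 up and 6 down of 20 (adjusted over the list alone, 6 and 7), with no camera call (adjusted p = 0.218). Bile acid genes fell in 11 of 23 (adjusted over the list alone, 13), such as Cyp27a1 (-2.72 ± 0.30; adjusted p = 7.96e-06). Fatty acid synthesis genes fell in 14 of 23 (adjusted over the list alone, 16), such as Mlxipl, the glucose sensor ChREBP (-2.77 ± 0.37; adjusted p = 1.47e-08).

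Also higher were Ccnd1, a G1 cyclin (1.77 ± 0.62), Igfbp1 (3.44 ± 0.98), Wwtr1 (0.55 ± 0.18), Ctgf (3.02 ± 0.58) and Ankrd1 (3.87 ± 0.86). Not called were Yap1 (0.08, adjusted p = 0.754), Cyr61 (-0.37, 0.749), Alb (-0.51, 0.196), Cyp7a1 (-4.0, 0.0761) and Hnf4a (-0.13, 0.618). The same held for Igf1 (-0.40, 0.241), Fgf21 (2.84, 0.127), Gdf15 (0.89, 0.376) and Inhba (-1.39, 0.141). In all 3967 of 13879 genes passed, 2197 higher and 1770 lower, with 1642 and 913 at least 2-fold. Muscle fibre markers fell in 11 of 14 (adjusted over the list alone, 12), from 288 ± 81.1 CPM in sham to 21.9 ± 23.9 CPM (adjusted p = 1.15e-05). The count was 2403 without sham replicate 1, 2382 without sham replicate 3 and 7187 with only these 2 groups in the fit. Ccnd1 was not called without any 1 sham or day 3 replicate 3, 4 or 5, nor Igfbp1 without sham replicate 1 or 3, nor Wwtr1 without any 1 sham or day 3 replicate 1, 2 or 4 (edgeR, adjusted p 0.0512 to 0.12). Cyp7a1 was -5.93 without day 3 replicate 1. Cyp7a1 was called without day 3 replicate 1 (edgeR, adjusted p = 0.024).

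At day 7 the comparison with sham asked what was altered in liver at the last day sampled. Division genes, matrix genes and macrophage markers were higher, and male-pattern, respiratory and fat-burning genes were lower. Sult1e1 rose by 7.85 ± 1.86, the wound-associated Sprr1a by 6.80 ± 1.34, Gpnmb, a glycoprotein of phagocytes, by 6.66 ± 1.18, the calcium channel gene Cacna1b by 6.64 ± 1.44, and the cystine transporter Slc7a11 by 5.93 ± 1.51. Ins2 had 1558 reads over the day 7 livers and 0 over sham, at least 359-fold higher against a floor of 3 counts over the sham group. These Ins2 reads too may come from a shared run. Hsd3b5 (-7.83 ± 1.18), the G protein regulator Rgs16 (-5.89 ± 1.39) and Slco1a1 (-4.95 ± 1.16) fell most. Next came the muscle genes Myh4 (-4.16 ± 1.39), Ttn (-4.03 ± 1.36) and Ryr1 (-4.02 ± 1.28), beside muscle fibre markers that fell in 10 of 14 (adjusted over the list alone, 13) (adjusted p = 7.81e-08), at 23.8 ± 33.4 CPM. Sprr1a was 8.33 without sham replicate 1, Gpnmb 7.52, Cacna1b 9.18 and Slc7a11 6.57 without sham replicate 2 and Sult1e1 7.25 and Cacna1b 6.04 without sham replicate 3. Cacna1b was 5.59 without day 7 replicate 2, Rgs16 -6.76 and Slco1a1 -6.50 without day 7 replicate 3 and Hsd3b5 -8.59 without day 7 replicate 4. Sult1e1 was 7.02, Gpnmb 5.96, Slc7a11 5.15, Myh4 -6.69, Ttn -6.04 and Ryr1 -5.86 without day 7 replicate 5. Sult1e1 and Slc7a11 were not called without sham replicate 1 or 3, nor Myh4, Ttn and Ryr1 without any 1 sham or day 7 replicate 1, 2, 3 or 4 (edgeR, adjusted p 0.0512 to 0.109). Ins2 was at least 228-fold higher without sham replicate 1, at least 235-fold higher without sham replicate 3 and at least 209-fold higher without day 7 replicate 2.

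Mitosis genes rose in 43 of 46 (adjusted over the list alone, 45), such as Anln (3.34 ± 0.73; adjusted p = 2.89e-12). S phase genes rose in 23 of 48 (adjusted over the list alone, 34), such as Gins2 (3.44 ± 0.82) and Mcm6 (3.11 ± 0.75; adjusted p = 2.56e-07). Mki67 stood at 106 ± 78.8 CPM (3.46 ± 0.97) and Ccnd1 rose by 2.18 ± 0.63. In day 7 replicate 3 Mki67 was at 1.43 CPM, below the sham libraries (7.67 to 10.6), and in the other day 7 livers at 74.7 to 218 CPM. Of the p53 targets, 10 of 23 (adjusted over the list alone, 12) rose, with Cdkn1a (4.85 ± 0.83; adjusted p = 5.06e-05). Macrophage and monocyte markers rose in 15 of 19 (adjusted over the list alone, 17), among them Trem2 (4.73 ± 0.92; adjusted p = 1.23e-07). Neutrophil markers rose in 5 of 9 (adjusted over the list alone, 8) (S100a8, 3.49 ± 0.98; adjusted p = 0.000534). Matrix genes rose in 26 of 35 (adjusted over the list alone, 30), including Col4a1 (2.11 ± 0.23; adjusted p = 2.32e-16). Cholangiocyte markers rose in 7 of 11 (adjusted over the list alone, 7), such as Cftr (3.23 ± 0.55) and Epcam (2.62 ± 0.66; adjusted p = 0.000182). Fetal and progenitor genes rose in 10 of 16 (adjusted over the list alone, 12), with Ly6d (5.62 ± 0.77) and Afp (3.49 ± 0.62; adjusted p = 3.25e-07). Acute phase proteins rose in 15 of 30 (adjusted over the list alone, 20), with Lcn2 (5.88 ± 1.01; adjusted p = 3.71e-05). The humoral factor list rose in 13 of 33 (adjusted over the list alone, 14), such as osteopontin, Spp1 (4.18 ± 0.85; adjusted p = 0.0116). Spp1 was 3.29 without day 7 replicate 1, Lcn2 5.23 without day 7 replicate 2 and Cdkn1a 4.14 without day 7 replicate 3. Gins2, Mcm6 and Epcam were not called without sham replicate 1 or 3, nor Mki67 and S100a8 without any 1 sham, nor Ccnd1 without any 1 sham or day 7 replicate 5 (edgeR, adjusted p 0.0509 to 0.0985).

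Nuclear genes of oxidative phosphorylation fell in 15 of 40 (adjusted over the list alone, 32), with small changes such as Sdha (-0.77 ± 0.17) and Ndufs3 (-0.57 ± 0.14; adjusted p = 5.52e-11). Fatty acid oxidation genes fell in 10 of 36 (adjusted over the list alone, 14), among them their regulator Ppara (-1.39 ± 0.36; adjusted p = 4.55e-07). Male-biased genes fell in 12 of 25 (adjusted over the list alone, 19), such as Cyp7b1 (-2.57 ± 0.45; adjusted p = 4.23e-14). P450 genes fell in 8 of 26 (adjusted over the list alone, 9), such as Cyp2c37 (-2.93 ± 0.54; adjusted p = 1.18e-05). Pericentral genes fell in 4 of 20 (adjusted over the list alone, 6), where Cyp2e1 fell (-2.38 ± 0.48) and Gstm3 rose (3.84 ± 0.71; adjusted p = 0.000566). Mature hepatocyte markers fell in 4 of 20 (adjusted over the list alone, 4) (adjusted p = 0.00659). Cyp2c37 was -3.65 and Cyp2e1 -3.05 without day 7 replicate 4. Ndufs3 was not called without sham replicate 1 or 3, nor Ppara without sham replicate 3 (edgeR, adjusted p 0.0566 to 0.0637).

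Ctgf (2.38 ± 0.56) and Ankrd1 (4.03 ± 0.86) were also higher. Not called were Yap1 (-0.17, adjusted p = 0.531), Wwtr1 (0.47, 0.0766), Cyr61 (0.47, 0.708), Alb (0.03, 0.954) and Cyp7a1 (-0.01, 0.999). Nor were Hnf4a (-0.43, 0.0966), Igf1 (-0.61, 0.0939), Igfbp1 (1.30, 0.314), Fgf21 (2.42, 0.211), Gdf15 (1.05, 0.324) and Inhba (-0.21, 0.862). In all 2658 of 13879 genes passed, 1722 higher and 936 lower, with 1388 and 363 at least 2-fold. The count was 919, 1248 or 782 without sham replicate 1, 2 or 3. Day 7 replicate 3 stood apart from the other day 7 livers, with Yap1 at 105 CPM against 60.6 to 68.2. Igfbp1 was 0.26 and Fgf21 -1.48 without day 7 replicate 3.

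**Figure D1:**
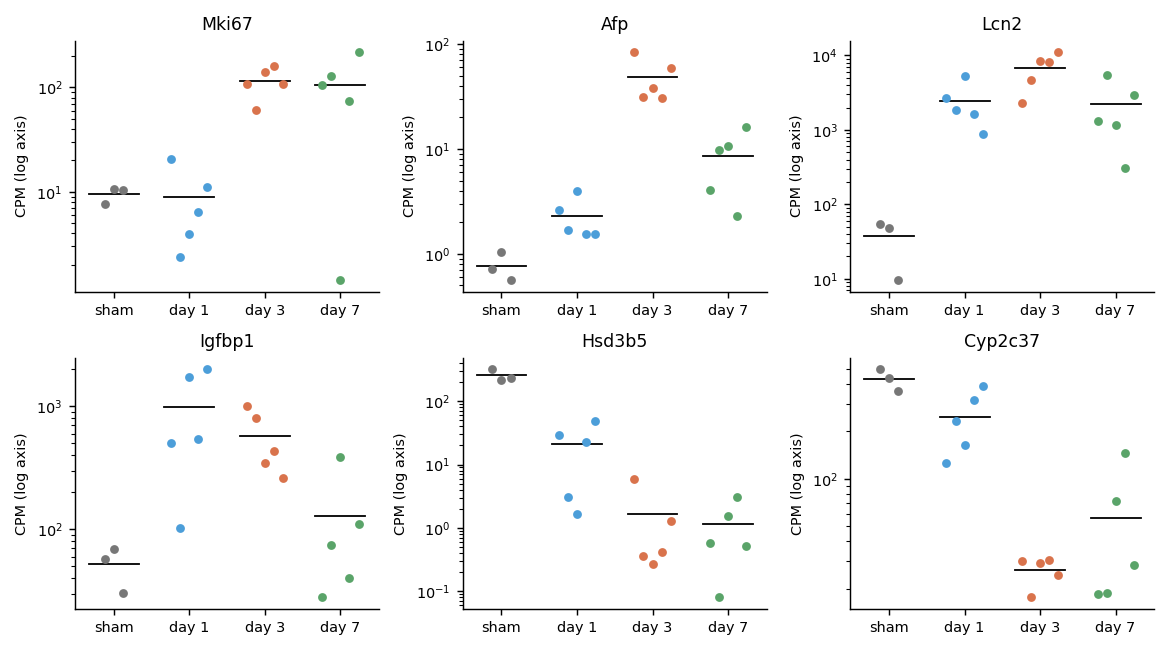
CPM of Mki67, Afp, Lcn2, Igfbp1, Hsd3b5 and Cyp2c37 in each liver library on a log axis, in sham (3 libraries) and at days 1, 3 and 7 after PHx (5 libraries each), with points for libraries and bars for group means. Mki67 averaged 9.56 CPM in sham and 116 CPM at day 3.

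Comparing days after PHx with each other leaves the sham libraries out. From day 1 to day 3 in liver, Afp rose by 4.38 ± 0.50 and Mki67 by 3.70 ± 0.79, and the steroid-reducing enzyme gene Akr1c18 by 5.71 ± 0.74. Islet transcripts rose too: Ins2 and Iapp had 0 reads at day 1 and were at least 1621-fold and 402-fold higher at day 3, and Gcg had 1 read, a ratio of 2147 (95% exact counting interval 385 to 84840). The P450 genes Cyp2c69 (-5.56 ± 0.75) and Cyp2c40 (-5.34 ± 0.70), Slco1a1 (-5.46 ± 1.15) and Sult2a8 (-5.22 ± 1.35) fell most. The early responders Gdf15 (-3.29 ± 0.65) and Cyr61 (-2.57 ± 0.70) fell as well. Yap1 (-0.06), Wwtr1 (-0.10), Ctgf (0.38), Ankrd1 (0.74), Ccnd1 (0.88), Alb (-0.47), Cyp7a1 (0.30), Hnf4a (-0.13), Igf1 (-0.26), Igfbp1 (-0.78), Fgf21 (-0.60), Lcn2 (1.49) and Inhba (-0.39) were not called, with adjusted p from 0.106 to 0.891. In all 3501 genes passed, 1611 higher and 1890 lower at day 3. The count was 2312 without day 1 replicate 4, and 596 with day 1 replicates 1 and 2 alone, which was chosen after seeing the data. Akr1c18 was 6.74 without day 1 replicate 1, Gdf15 -2.70 and Cyr61 -1.67 without day 1 replicate 5 and Cyp2c69 -6.23, Slco1a1 -7.13 and Sult2a8 -6.50 without day 3 replicate 1. Cyr61 was not called without day 1 replicate 5 (edgeR, adjusted p = 0.0567). Ccnd1 was 1.67 and Inhba 0.66 without day 1 replicate 1 and Cyp7a1 -1.65 without day 3 replicate 1. Ccnd1 was called without day 1 replicate 1 and Lcn2 without day 1 replicate 3 (edgeR, adjusted p 0.00485 to 0.0456). Gcg was at least 634-fold without day 1 replicate 5. Gcg was 1386-fold, Iapp at least 251-fold and Ins2 at least 1028-fold without day 3 replicate 3.

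The step from day 3 to day 7 in liver was read gene by gene. Scd1, the stearoyl-CoA desaturase, rose by 4.09 ± 0.74, the glutathione transferases Gstm3 and Gsta2 by 4.07 ± 0.57 and 3.31 ± 0.62, and Cyp2c54 by 3.20 ± 0.58. Afp (-2.49 ± 0.45), the steroid hydroxylase gene Cyp21a1 (-3.28 ± 0.59), Fam83a (-1.96 ± 0.39) and the imprinted gene Peg3 (-1.91 ± 0.43) fell. Mki67 was not called (-0.13, adjusted p = 0.965), nor were Yap1 (-0.25), Wwtr1 (-0.08), Cyr61 (0.84), Ctgf (-0.64), Ankrd1 (0.15), Ccnd1 (0.41), Alb (0.54) and Cyp7a1 (4.0). No call came for Hnf4a (-0.30), Igf1 (-0.20), Igfbp1 (-2.15), Fgf21 (-0.42), Gdf15 (0.16), Lcn2 (-1.62) and Inhba (1.17). In all 175 genes passed, 85 higher and 90 lower, against 2033 at an unadjusted p under 0.05. Without day 3 replicate 2, 3, 4 or 5 the count was 17, 37, 21 or 81, and without day 7 replicate 1, 2, 3 or 4 it was 37, 73, 626 or 59, while DESeq2 called 575 and the edgeR likelihood ratio test, chosen after seeing the data, 462. Scd1 was 5.00 and Cyp21a1 -2.69 without day 3 replicate 1 and Cyp2c54 2.19 without day 7 replicate 4. Scd1, Gsta2 and Cyp2c54 were not called without day 3 replicate 2, 3 or 4, nor Cyp21a1 without day 7 replicate 1, nor Fam83a without day 3 replicate 2, 3 or 4 or day 7 replicate 1, 2 or 4. Peg3 lost the call without day 3 replicate 1, 2, 3 or 4 or day 7 replicate 1, 2, 4 or 5 (edgeR, adjusted p 0.0509 to 0.128). Igfbp1 was -3.17 and Fgf21 -4.30 without day 7 replicate 3. Igfbp1 and Fgf21 were called without day 7 replicate 3 (edgeR, adjusted p 0.00166 to 0.0199).

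In quadriceps the question was whether resecting the liver changed gene expression in muscle, first at day 1. Stress and glucocorticoid-responsive genes rose within a day, and single genes of fat tissue, such as Adrb3 and Hcar1, fell. Trim63, the muscle ubiquitin ligase MuRF1, rose by 4.34 ± 1.03, from 79.99 ± 4.62 to 1623 ± 545 CPM. The largest rises were the cadherin gene Cdhr3 (6.76 ± 1.27), Ddit4, an inhibitor of mTORC1 (6.14 ± 1.27), the metallothionein Mt2 (5.94 ± 0.91), Lcn2 (5.79 ± 0.90), the transcription factor Maff (5.76 ± 1.41) and Tmem252 (5.54 ± 0.99). The largest falls were the adipocyte receptors Adrb3 (-6.17 ± 1.29) and Hcar1 (-6.13 ± 1.27), fatty acid synthase Fasn (-3.95 ± 1.11), Acvr1c (-3.92 ± 1.07), B3galt2 (-3.85 ± 0.87) and the elongase Elovl6 (-3.84 ± 1.0). Adrb3 was -4.75, Hcar1 -4.97, Fasn -3.21, Acvr1c -2.67, B3galt2 -3.26 and Elovl6 -3.16 without sham replicate 3, B3galt2 -4.84 without day 1 replicate 3 and Cdhr3 5.88 without day 1 replicate 4. Maff was 4.54, Tmem252 4.50, Adrb3 -7.42 and Fasn -4.57 without day 1 replicate 5. edgeR called none of these without any 1 sham (adjusted p 0.0508 to 0.243 for calls lost). It called only Mt2 and Lcn2 without day 1 replicate 2 and only Cdhr3, Ddit4, Mt2, Lcn2 and Tmem252 without day 1 replicate 4. It called only Cdhr3, Mt2, Lcn2, Tmem252 and Adrb3 without day 1 replicate 5 and all but Fasn and Acvr1c without day 1 replicate 1. It called all but Fasn, Acvr1c and Elovl6 without day 1 replicate 3.

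Glucocorticoid receptor targets rose in 17 of 26 (adjusted over the list alone, 21), including Fkbp5 (3.75 ± 0.66) and Mt1 (4.95 ± 0.76; adjusted p = 4.03e-18). Atrogenes, the genes induced in wasting muscle, rose in 11 of 36 (adjusted over the list alone, 24), such as Foxo1 (3.03 ± 0.64; adjusted p = 4.38e-13). Klf15 (2.21 ± 0.62), Cebpd (4.32 ± 1.07) and Pdk4, which restrains glucose oxidation (4.12 ± 1.09), rose. Fbxo32, the ligase atrogin-1, stood at 2338 ± 1511 CPM against 293 ± 17.1 in sham but was not called (2.99, adjusted p = 0.0576). Targets of p53 rose in 5 of 21 (adjusted over the list alone, 10), with Cdkn1a (4.97 ± 0.91) and Btg2 (4.36 ± 1.05; adjusted p = 0.000105). JAK-STAT3 and NF-kB response genes rose in 9 of 30 (adjusted over the list alone, 14), such as Junb (3.90 ± 0.86; adjusted p = 8.62e-05). Neutrophil markers rose in 4 of 8 (adjusted over the list alone, 5) (adjusted p = 4.51e-05). Ribosome biogenesis genes rose in 5 of 35 (adjusted over the list alone, 22), such as Odc1 (1.90 ± 0.42; adjusted p = 1.26e-09). Of the proteasome subunits edgeR called 0 of 34 (adjusted over the list alone, 0), with 9 at an unadjusted p under 0.05 and 2 by DESeq2. Psmd11 stood at 1.10, and camera called the list up (adjusted p = 9.51e-07). The humoral factor list rose in 3 of 24 (adjusted over the list alone, 7), such as the receptor Tnfrsf12a (3.23 ± 0.59; adjusted p = 0.0126). Interferon response genes fell in 6 of 33 (adjusted over the list alone, 22), such as Oasl2 (-2.21 ± 0.52) and Psmb9 (-2.19 ± 0.55; adjusted p = 2.46e-12). Oasl2 was -2.81 without day 1 replicate 1 and Junb 2.71 without day 1 replicate 5. edgeR called none of these without any 1 sham (adjusted p 0.0502 to 0.2 for calls lost). It called only Mt1 without day 1 replicate 2 and only Fkbp5, Mt1, Cdkn1a, Junb, Odc1 and Tnfrsf12a without day 1 replicate 4. It called only Fkbp5, Mt1, Cdkn1a, Junb and Tnfrsf12a without day 1 replicate 5 and all but Klf15, Cebpd, Pdk4 and Psmb9 without day 1 replicate 3.

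Adipocyte markers fell in 1 of 11 (adjusted over the list alone, 8), that member being Adrb3 (adjusted p = 2.92e-05). The adipocyte hormone gene Adipoq stood at 168 ± 154 CPM in sham, with 345 CPM in sham replicate 3, and at 15.8 ± 16.02 CPM at day 1. Hepatocyte transcripts were also present in muscle, at 2.06 to 4.86 CPM in sham and 2.97 to 118 CPM at day 1. Hepatocyte markers rose in 1 of 19 (adjusted over the list alone, 15) (adjusted p = 0.000153), that member being Tat, with 207 reads against 0 in sham, at least 50.2-fold higher against a floor of 3 counts over the sham group. Ankrd1, a stretch-responsive YAP target, rose by 3.36 ± 0.67. Not called were Yap1 (0.54, adjusted p = 0.188), Fbxo30 (1.44, 0.162), Socs3 (0.69, 0.583), Stat3 (0.45, 0.19), Mstn (0.69, 0.26) and Igf1 (-0.41, 0.627). The myosins were not called either, Myh1 (1.59, 0.192), Myh2 (1.79, 0.375), Myh4 (0.02, 0.973) and Myh7 (6.68, 0.0993). edgeR did not call Ankrd1 without any 1 sham or day 1 replicate 2 (adjusted p 0.0549 to 0.177). Socs3 was -0.90 without day 1 replicate 5. Tat was at least 31.8-fold without sham replicate 2.

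In all 720 of 13601 genes passed, 413 higher and 307 lower, with 327 and 255 at least 2-fold, against 3693 at an unadjusted p under 0.05. edgeR called 0 genes without sham replicate 1, 2 or 3, where 2899, 2674 and 2373 passed unadjusted, and 1292, 4, 390, 106 or 61 without day 1 replicate 1, 2, 3, 4 or 5. With all libraries DESeq2 called 1804, the 2 groups alone gave 2259, and, in settings chosen after seeing the data, the likelihood ratio test gave 1609 while edgeR called 0 with an adipocyte covariate (1255 unadjusted) and 0 with the day 1 libraries that hold islet reads, replicates 1 to 3 (2955 unadjusted).

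Day 3 asked how far the muscle response had gone when the liver was dividing. It was the day with the most calls in quadriceps: protein breakdown genes rose together, and genes of matrix, fat and lipid synthesis fell. Fbxo32 rose by 4.74 ± 0.99, from 293 ± 17.1 to 7832 ± 2722 CPM, and Trim63 by 5.30 ± 1.09, to 3163 ± 1602 CPM. The largest rises were Doc2b, a calcium sensor of vesicle fusion (8.76 ± 1.28), Lcn2 (7.78 ± 0.97), the metallothioneins Mt2 (7.25 ± 0.97) and Mt1 (6.43 ± 0.82), Ddit4 (6.24 ± 1.28) and the thioesterase Acot1 (6.16 ± 1.30). Adrb3 (-8.44 ± 1.51), Nnat (-7.09 ± 1.65), Hcar1 (-6.57 ± 1.29), Scd1 (-6.41 ± 1.51), Fasn (-6.10 ± 1.21) and Elovl6 (-5.74 ± 1.10) fell most. Adrb3 was -7.02, Nnat -5.74, Hcar1 -5.40, Scd1 -5.25, Fasn -5.35 and Elovl6 -5.07 without sham replicate 3 and Hcar1 -7.88 without day 3 replicate 3.

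Every proteasome subunit tested rose, 34 of 34 (adjusted over the list alone, 34), such as Psmb4 (2.13 ± 0.29; adjusted p = 2.35e-18). Atrogenes rose in 28 of 36 (adjusted over the list alone, 29) and fell in 2, with Map1lc3b (2.12 ± 0.31) and Fbxo31 (2.90 ± 0.43) higher (adjusted p = 1.02e-08). Autophagy and lysosome genes rose in 23 of 35 (adjusted over the list alone, 23), such as the protease Ctsl (3.04 ± 0.50) and the mitophagy receptor Bnip3l (1.91 ± 0.33; adjusted p = 8.56e-07). Glucocorticoid receptor targets rose in 21 of 26 (adjusted over the list alone, 22), with Fkbp5 (4.19 ± 0.68; adjusted p = 1.1e-08). Ribosome biogenesis genes rose in 27 of 35 (adjusted over the list alone, 30), such as Ncl (1.46 ± 0.23; adjusted p = 1.1e-08). Stress response genes rose in 14 of 32 (adjusted over the list alone, 14), such as Atf4 (2.03 ± 0.43; adjusted p = 0.0118). Fatty acid oxidation genes rose in 15 of 36 (adjusted over the list alone, 15), such as Acadl (1.89 ± 0.39; adjusted p = 0.00257). JAK-STAT3 and NF-kB response genes rose in 15 of 30 (adjusted over the list alone, 15), including Il6ra (4.52 ± 0.78) and Stat3 (1.27 ± 0.22; adjusted p = 0.00581). Neutrophil markers rose in 5 of 8 (adjusted over the list alone, 6) (S100a8, 4.95 ± 1.14; adjusted p = 0.011). S100a8 was 8.85 without sham replicate 3.

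Matrix genes fell in 20 of 35 (adjusted over the list alone, 20), among them Col6a1 (-3.19 ± 0.41; adjusted p = 9.51e-07). Fibroblast markers fell in 5 of 17 (adjusted over the list alone, 5), such as Col1a1 (-4.28 ± 0.73) and Lum (-3.61 ± 0.59; adjusted p = 0.0195). Adipocyte markers fell in 11 of 11 (adjusted over the list alone, 11), with Retn (-4.26 ± 1.13; adjusted p = 0.00123), beside Adipoq at 7.24 ± 4.39 CPM. Interferon response genes fell in 15 of 33 (adjusted over the list alone, 15), such as Gbp7 (-2.06 ± 0.44; adjusted p = 0.000136). Cholesterol synthesis genes fell in 11 of 24 (adjusted over the list alone, 12), such as Idi1 (-1.85 ± 0.37), while Fdft1 rose (2.69 ± 0.42; adjusted p = 0.00641). Glycolysis and glycogen genes fell in 9 of 23 (adjusted over the list alone, 9) and rose in 3, with Phkg1 (-2.95 ± 0.37) and Pgam2 (-2.47 ± 0.45) lower (adjusted p = 0.0438). Muscle fibre markers fell in 7 of 14 (adjusted over the list alone, 7), such as the calcium store protein Casq1 (-3.43 ± 0.48; adjusted p = 0.0173), and together stood at 65.2% ± 6.54 of their sham level (SD, n = 5). Sarcomere and myosin genes went both ways, 7 up and 9 down of 32, with a median of -0.24 and a mean of 0.87, and were not called as a list (adjusted p = 0.368). Retn was -3.09 without sham replicate 3 and Col1a1 -5.46 without day 3 replicate 5.

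Foxo1 (2.96 ± 0.64), Fbxo30 (2.14 ± 0.67), Klf15 (2.80 ± 0.64), Cebpd (5.33 ± 1.13), Pdk4 (4.71 ± 1.12), Ankrd1 (3.91 ± 0.69) and the slow myosin Myh7 (7.48 ± 2.52) rose. So did Yap1 (0.82 ± 0.26), from 48.99 ± 3.44 to 86.7 ± 19.2 CPM, and Mstn, the growth inhibitor myostatin (1.02 ± 0.40), while Igf1 fell (-1.93 ± 0.51). Socs3 (-0.46, adjusted p = 0.639), Myh1 (1.49, 0.117), Myh2 (0.84, 0.587) and Myh4 (-0.60, 0.173) were not called. Hepatocyte transcripts ranged from 2.62 to 226 CPM. In all 6454 of 13601 genes passed, 3379 higher and 3075 lower, with 1806 and 1998 at least 2-fold, and 719 with an adipocyte covariate, a setting chosen after seeing the data that also turned the Retn change to 0.56 (adjusted p = 0.615). Myh7 was 6.03 without day 3 replicate 5. Fbxo30 was not called without sham replicate 2 or 3, nor Myh7 without any 1 sham, nor Yap1 without sham replicate 3. Mstn lost the call without any 1 sham or day 3 replicate 1, 2, 3 or 4 (edgeR, adjusted p 0.0519 to 0.134). Socs3 was 0.51 without sham replicate 2 and Myh2 -0.01 without day 3 replicate 5.

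At day 7 the question was what was left of the muscle response. edgeR called 8 genes, 6 higher and 2 lower, and 1604 at an unadjusted p under 0.05. Sln, the SERCA inhibitor sarcolipin, rose by 5.39 ± 0.87, Lcn2 by 5.36 ± 0.88, Ccdc136 by 2.67 ± 0.46 and the tubulin Tubb6 by 1.86 ± 0.33. Mrln, which encodes the SERCA inhibitor myoregulin, fell (-1.52 ± 0.26), as did Gid4 (-0.92 ± 0.15). The other rises were Gnmt (5.35 ± 0.79) and Klhl3 (2.50 ± 0.44), named after their values were seen. Sln was 4.41 without day 7 replicate 2. Sln was not called without any 1 sham or day 7 replicate 5, nor Lcn2, Ccdc136, Tubb6, Mrln and Gid4 without any 1 sham or day 7 replicate 2 or 5 (edgeR, adjusted p 0.0686 to 0.32).

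None of the fixed muscle genes passed: Fbxo32 was at 1641 ± 1801 CPM (2.48, adjusted p = 0.266), Trim63 at 622 ± 942 CPM (2.96, 0.227), and Ankrd1 came nearest (3.72, 0.0552). Adjusted p lay between 0.0932 and 0.958 for Foxo1 (1.85), Fbxo30 (1.0), Fkbp5 (2.68), Klf15 (1.16), Cebpd (3.25), Mt1 (3.02), Mt2 (3.70), Pdk4 (2.97) and Ddit4 (4.43). The range also covers Socs3 (-0.62), Stat3 (0.04), Mstn (-0.26), Igf1 (-0.66), Myh1 (2.64), Myh2 (2.85), Myh4 (-0.98), Myh7 (7.93) and Yap1 (0.37). camera called the denervation and regeneration genes up (adjusted p = 2.76e-09), with 1 of 23 (list alone, 12) rising, namely Sln. Embryonic myosin Myh3 was at 6.24, with 84.6 CPM in replicate 2 and 1.84 to 23.3 in the others. camera also called proteasome subunits up (adjusted p = 4.01e-09). edgeR called 0 of 34 (list alone, 0), 14 unadjusted and DESeq2 1, with Psmd4 at 1.26. edgeR called 0 of 36 atrogenes (list alone, 14), 17 unadjusted and DESeq2 10, with Eif4ebp1 at 2.09. The list's camera adjusted p was 1.29e-05. Glucocorticoid receptor targets (camera adjusted p = 8.65e-09) rose in 1 of 26 (list alone, 11), namely Lcn2. Of the adipocyte markers (camera adjusted p = 1.3e-06) edgeR called lower 0 of 11 (list alone, 1), 2 unadjusted and DESeq2 0. Nnat changed by -4.75 and Adipoq stood at 72.5 ± 112 CPM. Of the glycolysis genes (camera adjusted p = 0.00038) edgeR called lower 0 of 23 (list alone, 0), 10 unadjusted and DESeq2 0. Pkm stood at -0.84. Socs3 was 0.35 without sham replicate 2, Fbxo32 1.64, Trim63 1.37, Foxo1 1.16, Fbxo30 0.14, Fkbp5 2.06, Cebpd 1.53, Pdk4 1.25 and Ddit4 2.27 without day 7 replicate 3 and Nnat -7.57 without day 7 replicate 4. Ankrd1 was called without day 7 replicate 1, 3 or 4, Fkbp5, Mt1 and Mt2 without day 7 replicate 1 or 4, Eif4ebp1 without day 7 replicate 1 and Nnat without day 7 replicate 4 (edgeR, adjusted p 0.0307 to 0.05).

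Day 7 replicate 3 held Trim63 at 2285 CPM and Pdk4 at 10236 CPM. The count of 8 became 0 without sham replicate 1, 2 or 3 or day 7 replicate 5 (1189, 997, 1032 and 1292 unadjusted), and 47, 2, 19 or 51 without day 7 replicate 1, 2, 3 or 4. DESeq2 called 292 and the 2 groups alone gave 2, and, chosen after seeing the data, the likelihood ratio test gave 150 and the adipocyte covariate 0 (641 unadjusted).

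**Figure D2:**
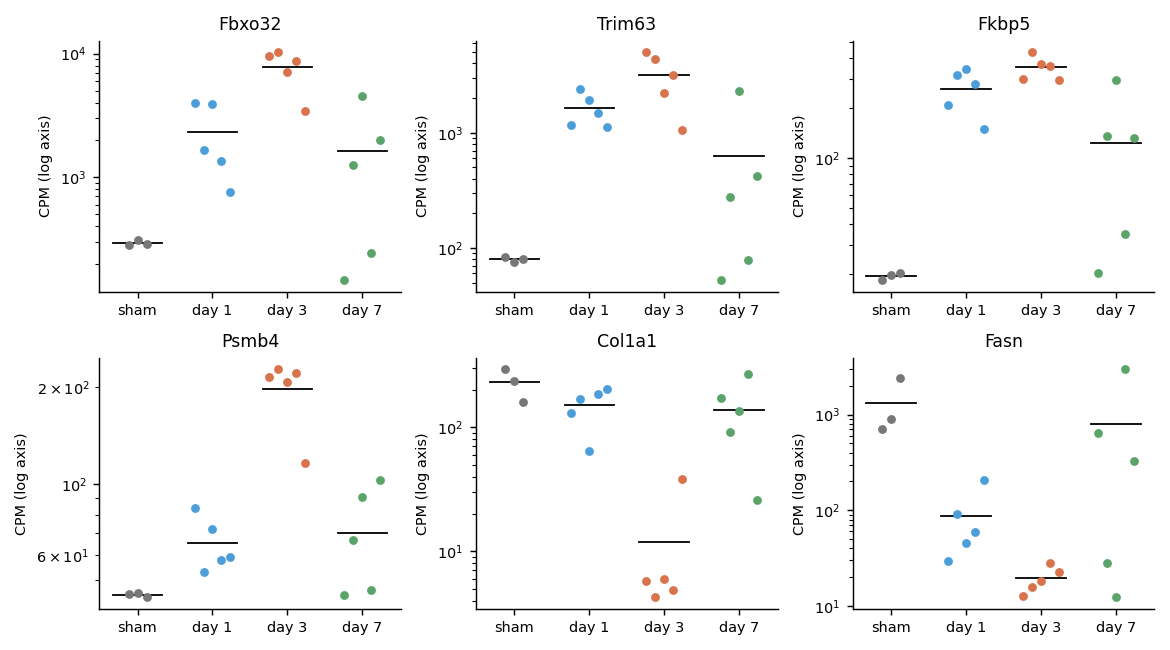
CPM of Fbxo32, Trim63, Fkbp5, Psmb4, Col1a1 and Fasn in each quadriceps library on a log axis, in sham and at days 1, 3 and 7 after PHx, with bars for group means. Trim63 averaged 79.99 CPM in sham and 3163 CPM at day 3.

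Between days in muscle, day 1 to day 3 moved the lipid sensor Ffar4 (5.64 ± 0.92), Fam65c (5.59 ± 0.75), the keratin Krt80 (4.99 ± 0.86) and Perp (3.89 ± 0.60) up. Mybph, a myosin-binding protein (-4.64 ± 0.94), Dio2, which activates thyroid hormone (-4.24 ± 0.90), the myosin kinase gene Mylk4 (-4.03 ± 0.64) and the calcium receptor Casr (-3.99 ± 0.56) moved down. Mt1 (1.48 ± 0.52) and Stat3 (0.82 ± 0.19) rose and Igf1 fell (-1.52 ± 0.46). Not called were Fbxo32 (1.74, adjusted p = 0.0716), Trim63 (0.96), Foxo1 (-0.07), Fbxo30 (0.70) and Fkbp5 (0.44). Also uncalled were Klf15 (0.59), Cebpd (1.01), Mt2 (1.31), Pdk4 (0.59), Ddit4 (0.10), Socs3 (-1.15) and Mstn (0.33). Of structural and YAP genes none was called, Myh1 (-0.10), Myh2 (-0.95), Myh4 (-0.62), Myh7 (0.80), Yap1 (0.29) and Ankrd1 (0.55). In all 3564 genes passed, 1853 higher and 1711 lower, and 1368 with day 1 replicates 1 to 3 alone, chosen after seeing the data. Mybph was -4.01 without day 1 replicate 4, Ffar4 6.31 and Dio2 -1.91 without day 1 replicate 5 and Mybph -5.35 without day 3 replicate 5. Mt1 was not called without day 1 replicate 1, 2, 3 or 4 or day 3 replicate 2, 3 or 4, nor Igf1 without day 1 replicate 1 or 5 or day 3 replicate 4 (edgeR, adjusted p 0.0514 to 0.0928). Myh2 was 0.13 without day 1 replicate 3, Socs3 0.45 without day 1 replicate 5 and Myh7 -0.65 without day 3 replicate 5. Mt2 was called without day 1 replicate 5 (edgeR, adjusted p = 0.0469).

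From day 3 to day 7 in muscle, Fbxo32 (-2.25 ± 0.71), Trim63 (-2.35 ± 0.76), Fkbp5 (-1.51 ± 0.49), Klf15 (-1.64 ± 0.50), Cebpd (-2.08 ± 0.77), Mt1 (-3.41 ± 0.56), Mt2 (-3.56 ± 0.64), Stat3 (-1.23 ± 0.19) and Mstn (-1.29 ± 0.34) fell, and Igf1 rose (1.28 ± 0.46). The largest rises were Casr (3.62 ± 0.55), Map3k7cl (3.60 ± 0.61), the collagen Col6a3 (3.27 ± 0.53) and the protease Adamts20 (3.09 ± 0.57), and the largest falls Fam65c (-4.83 ± 0.70), Mlph (-3.87 ± 0.60), Mt2 and Doc2b (-3.56 ± 0.77). Foxo1 (-1.11, adjusted p = 0.0831), Fbxo30 (-1.14), Pdk4 (-1.74), Ddit4 (-1.81), Socs3 (-0.16), Myh1 (1.14), Myh2 (2.0), Myh4 (-0.38), Myh7 (0.46), Yap1 (-0.46) and Ankrd1 (-0.19) were not called. In all 4971 genes passed, 2315 higher and 2656 lower at day 7. Fbxo32 was -3.10, Trim63 -3.94, Fkbp5 -2.12, Cebpd -3.80, Fam65c -5.66 and Doc2b -4.82 without day 7 replicate 3. Trim63 was not called without day 3 replicate 1 or 2 or day 7 replicate 2, nor Fkbp5 without day 3 replicate 2 or day 7 replicate 4, nor Klf15 without day 3 replicate 2. Cebpd lost the call without day 3 replicate 1, 2 or 4 or day 7 replicate 1, 2, 4 or 5 and Igf1 without day 3 replicate 2, 3, 4 or 5 or day 7 replicate 1 or 4 (edgeR, adjusted p 0.0505 to 0.134). Myh7 was -1.45 without day 7 replicate 2 and Foxo1 -1.81, Fbxo30 -2.0, Pdk4 -3.46 and Ddit4 -3.98 without day 7 replicate 3. Foxo1, Pdk4, Ddit4 and Yap1 were called without day 7 replicate 3, Fbxo30 without day 3 replicate 5 or day 7 replicate 3 and Myh1 without day 3 replicate 5 (edgeR, adjusted p 0.000221 to 0.0456).

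A further test asked which genes responded differently in the tissues, as the change in liver minus the change in quadriceps over 36 libraries. At day 1 the liver change lay above that in muscle for Hcar2, a ketone body receptor (7.37 ± 1.58), the lipid droplet gene Cidec (6.52 ± 2.07), Cntnap1 (5.85 ± 1.20) and Npnt (5.72 ± 1.43), and also for Ccnd1 (3.00 ± 0.86). It lay below for Fbxo32 (-3.19 ± 0.95), Foxo1 (-2.48 ± 0.65) and Klf15 (-3.80 ± 0.74), and of these Klf15 fell in liver (-1.59 ± 0.38) and rose in muscle. The largest differences below were hepatocyte transcripts that gained reads in muscle: F2 (adjusted p = 0.00624), Apoa2 (0.0106), Tat (0.0363) and Hao1 (0.0307), each with 0 reads in sham quadriceps, and Hnf4a was called too (0.0336). Differences were not called for Yap1 (-0.39), Wwtr1 (0.26), Cyr61 (-1.52), Ctgf (1.23), Ankrd1 (-0.30), Mki67 (0.57), Alb (-4.36), Igf1 (0.27), Igfbp1 (0.03) and Lcn2 (0.23). Of the muscle genes uncalled differences were Trim63 (-3.50), Fbxo30 (-0.90), Fkbp5 (-2.04), Cebpd (-1.08), Mt1 (0.93), Mt2 (0.88), Pdk4 (1.76) and Ddit4 (-2.16). The last were Socs3 (1.09), Stat3 (0.34), Myh1 (-1.47), Myh2 (-1.41) and Myh4 (-0.70). In all 1430 of 12780 genes differed, 839 above and 591 below. The count was 893 or 826 without liver sham replicate 1 or 3, and 950, 924 or 825 without quadriceps sham replicate 1, 2 or 3.

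At day 3 the tissues differed in 5302 genes, 2545 above and 2757 below, and 773 of these were called in opposite directions. Col1a1 rose in liver (3.91 ± 0.79) and fell in muscle (-4.28 ± 0.73), a difference of 8.17 ± 1.17, as did Fam83a (adjusted p = 1.65e-06, with 3 reads in muscle at day 3) and Ccnd1 (4.57 ± 0.89). Mki67 (4.85 ± 1.33) and Igf1 (1.52 ± 0.61) also lay above in liver. The liver change lay below for Doc2b (-9.29 ± 1.82), Trim63 (-7.34 ± 1.49), Fbxo32 (-5.65 ± 1.0), Klf15 (-3.94 ± 0.75), Foxo1 (-3.22 ± 0.66), Fbxo30 (-2.25 ± 0.69), Fkbp5 (-2.28 ± 0.80), Cebpd (-3.08 ± 1.06), Ddit4 (-3.13 ± 1.22) and Myh1 (-4.63 ± 1.49). Islet genes Ins2 and Gcg rose in liver and fell in muscle, where Ins2 had 389 reads in sham and 0 at day 3, at least 205-fold lower against a floor of 3 counts over the day 3 group (interaction adjusted p = 6.88e-05 and 1.67e-05). Hepatocyte transcripts in muscle gave Gc (0.00391), Ces3a (0.000642), Apoa2 (0.000341), Alb (0.0196) and Hnf4a (0.0263). Of these Ces3a (-4.54) and Apoa2 (-1.755) also fell in liver. Not called were Yap1 (-0.75, adjusted p = 0.0528), Wwtr1 (-0.65), Cyr61 (-1.77), Ctgf (1.82), Ankrd1 (-0.05), Igfbp1 (0.30) and Lcn2 (-0.29). Uncalled too were Mt1 (-1.70), Mt2 (-1.79), Pdk4 (-1.43), Socs3 (1.56), Stat3 (-0.63), Myh2 (-2.85) and Myh4 (-3.72). In muscle Col1a1 was -5.46 without day 3 replicate 5 and Ins2 at least 92.1-fold lower without sham replicate 1.

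At day 7, 905 genes differed, 567 above and 338 below. Liver lay above in the elongase Elovl7 (5.16 ± 1.08), Cd14 (4.98 ± 1.39), Mybl1 (4.62 ± 0.84) and Ccnd1 (2.88 ± 0.85), and in Ins2 (adjusted p = 0.0022). It lay below in Rgs16 (-7.73 ± 1.82), Doc2b (-7.05 ± 1.81), the slow troponin Tnnt1 (-6.81 ± 1.95), Myh1 (-6.40 ± 1.56), Fbxo32 (-3.90 ± 0.96), Trim63 (-5.70 ± 1.5) and Foxo1 (-2.35 ± 0.65), of which Myh1 fell in liver (-3.76 ± 1.22) with the muscle reads there. The other fixed genes reported were not called, namely Yap1 (-0.55), Wwtr1 (0.19), Cyr61 (-0.90), Ctgf (1.44), Ankrd1 (0.29), Mki67 (2.73), Alb (-3.27), Hnf4a (-3.85), Igf1 (0.03), Igfbp1 (-0.87) and Lcn2 (0.51). Of the muscle genes these were Fbxo30 (-1.12), Fkbp5 (-1.32), Klf15 (-2.18), Cebpd (-1.89), Mt1 (0.14), Mt2 (0.31), Pdk4 (-2.01) and Ddit4 (-2.18). The others were Socs3 (-0.01), Stat3 (-0.31), Myh2 (-5.57) and Myh4 (-3.21). The count was 403, 547 or 371 without liver sham replicate 1, 2 or 3, 534 or 598 without liver day 7 replicate 1 or 2, 529, 458 or 440 without quadriceps sham replicate 1, 2 or 3, and 1481 by DESeq2.

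Tissues share no library, so genes called in both can be counted, though sharing of animals is not stated. At day 1, 182 genes rose in both against 65.7 expected from the counts (Fisher's exact test, p = 3.2e-44). Falls in both numbered 71 against 30.3 (exact p = 3.71e-12). Both need the quadriceps calls, 0 by edgeR without any 1 sham (2373 to 2899 unadjusted, 1804 by DESeq2 with all libraries). Shared rises included Mt1, Mt2, Lcn2, Cdkn1a, Ddit4, Btg2, Cebpd, Ankrd1, Pdk4, the clock genes Arntl and Nfil3, and the neutrophil marker Retnlg. At day 3, 365 rose in both against 485 expected (Fisher's exact test, p = 2.52e-12). With calls also at least 2-fold the direction turned, to 204 against 179 expected (exact p = 0.0377). Falls in both numbered 433 against 330 (exact p = 2.91e-11). At day 7 counts were 2 higher (Lcn2 and Tubb6) and 1 lower (Gid4), with p of 0.0679 and 0.0652. DESeq2 gave 48 and 10 against 33 and 5.87 expected (exact p = 0.0076 and 0.0801). At 2-fold the 2 rises had exact p = 0.0422. Genes are not independent replicates, so p describes the overlap of gene sets.

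As the title names hepatic Yap1, its RNA and that of genes it is known to drive were read across days. YAP protein and activity were not measured. Yap1 (mm10 chromosome 9, 7932001 to 8004596) stood at 81.03 ± 6.83 CPM in sham liver and at 89.3 ± 14.6, 85.9 ± 6.701 and 72.2 ± 18.4 CPM at days 1, 3 and 7, and was called at none of them by edgeR. Of 28 YAP and TAZ targets in liver, 11 rose and 2 fell at day 1 (adjusted over the list alone, 12 and 2), with Gadd45b (5.09 ± 1.01) among the rises, and camera did not call the list (adjusted p = 0.082). At day 3 the numbers were 6 and 1 (list alone, 6 and 1), with Ajuba (2.08 ± 0.37) higher and no call (adjusted p = 0.0583). At day 7 they were 6 and 0 (list alone, 7 and 0), with Ajuba (2.30 ± 0.37) higher, and the list was called up (adjusted p = 0.036). In quadriceps Yap1 rose at day 3, and camera called its targets at no day (adjusted p = 0.234, 0.818 and 0.504). Cyr61 (3.73 ± 0.77) was higher at day 1. Ankrd1 and Igfbp3 (3.55 ± 0.76) were higher and Tgfb2 (-1.40 ± 0.39) lower at day 3. In liver Gadd45b was 4.47 without day 1 replicate 5. For quadriceps day 1, Cyr61 was 3.00 without day 1 replicate 5, and edgeR did not call Cyr61 without any 1 sham or day 1 replicate 2 (adjusted p 0.0549 to 0.177). In quadriceps Igfbp3 was 2.78 without day 3 replicate 1.

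**Figure D3:**
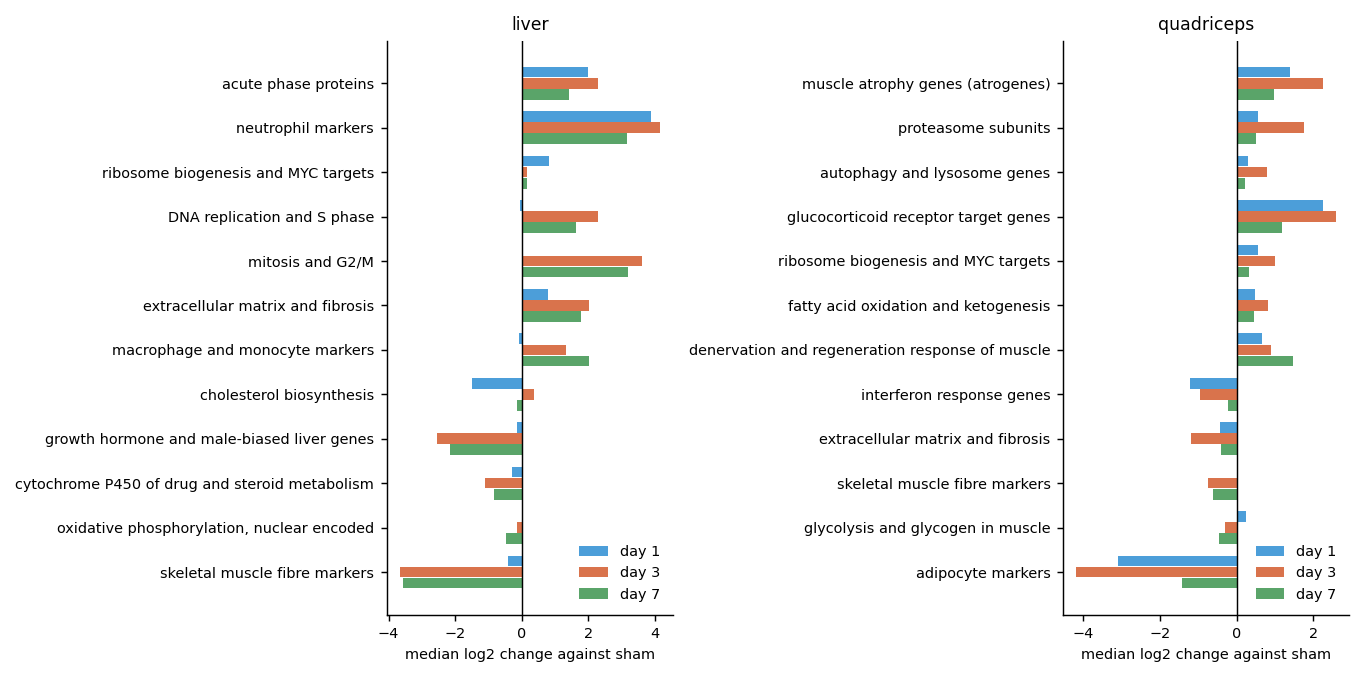
Median log2 change of the tested members of 12 fixed gene lists in liver and of 12 in quadriceps at days 1, 3 and 7 after PHx against sham, as bars from 0. In quadriceps the proteasome median was 0.55, 1.76 and 0.50 at days 1, 3 and 7.

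**Figure D4:**
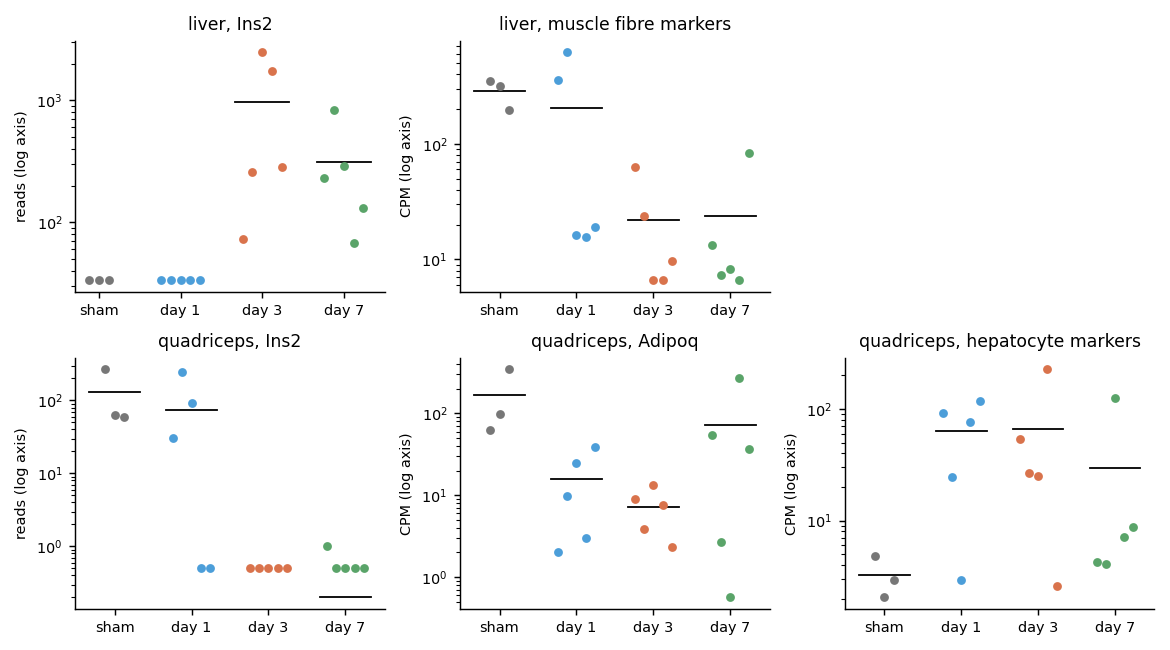
Reads of Ins2 and CPM of muscle fibre markers in each liver library, and reads of Ins2, CPM of Adipoq and CPM of hepatocyte markers in each quadriceps library, by group, on log axes with libraries at 0 drawn at the foot. Ins2 had 10 or more reads in all day 3 and day 7 livers and all sham quadriceps libraries.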

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

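The tests of the identity and depth of day 7 replicate 3, of the islet reads and of the fat genes were chosen only after the results were seen, and the day 3 test given here replaced another once that had not decided: of genes that separate day 3 from the other day 7 libraries replicate 3 took the day 7 side in 23.4% in liver, above the day 3 libraries (up to 16.2%), and in 20.7% in quadriceps, within them (up to 60.9%). Day 7 replicate 3 looked like an earlier library in both tissues, with Trim63 at 2285 CPM in quadriceps (other day 7 libraries 52.5 to 422) and Fgf21 at 50.6 CPM in liver (0.0943 to 1.12). A day 3 source is argued against by the second test only: of genes that separate days 1 and 3 it took the day 3 side in 20.1% in liver and 21.6% in quadriceps, where day 3 libraries left out in turn gave at least 82.2% and 41.9%. So is low depth (totals of 19009058 counts or more). A day 1 sample under a day 7 label may be the source, since of 652 liver and 164 quadriceps genes that separate day 1 from the other day 7 libraries it took the day 7 side in 9.82% and 14.6%, within the day 1 libraries left out in turn (up to 41.02% and 50.7%). A slower animal at day 7 stays open (not tested). Mrln (8.19 CPM) and Ccdc136 (14.1 CPM) in its quadriceps lay outside the day 1 range (17.0 to 26.4 and 1.76 to 5.49). Its 292 liver Ins2 reads may come from a shared run and cannot decide.

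Islet hormone transcripts stood in liver at days 3 and 7, with 10 or more Ins2 reads in 5 of 5 libraries each, and in no other liver. The hepatectomised liver as the only source is argued against by 3 of 3 sham quadriceps libraries with as many. An islet library sharing a run may be a source: 6 sham and day 1 quadriceps libraries held as many. Over 12 islet genes liver and quadriceps profiles correlated (Pearson r = 0.808, just over the bound set). Whole pancreas is argued against, as 12 of 12 islet but 1 of 18 acinar genes (Cela1) are in the table. Islet cells arising in the regrowing liver are not excluded for the liver reads.

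Fat genes fell in quadriceps at day 3. There 6 fat synthesis genes (-3.89, mean log2) lay 0.13 above 6 adipocyte identity genes (-4.02). A single fat-rich sham library is argued against, since without sham replicate 3 (Adipoq 345 CPM) 6 of 11 markers were still called lower, exactly the bound set. Less fat tissue in the muscle samples may be the cause, as the gene sets moved alike. Whether the mice lost fat or less was dissected stays open.

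The tissues differed in 1430, 5302 and 905 genes at days 1, 3 and 7. Of 461 measures over groups of 5 libraries, 94 had a library far from the other 4. Chance gives about 1 in 20 (23.1) only for normal, independent measures, so no excess is drawn. The 94 follow in CPM, with the others' range in brackets.

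In liver at day 1, replicate 1 had Cyp7a1 at 90.5 (others 5.37 to 29.9), Inhbb at 17 (47.6 to 54.6) and Tnfsf10 at 2.89 (0.444 to 1.13). Replicate 2 had Trim63 at 4.61 (0.142 to 0.705). Replicate 3 had Fgf21 at 38.3 (14.2 to 19.3) and Serpina3n at 11642 (3552 to 4677). Replicate 5 had Ankrd1 at 2.37 (0.425 to 0.843), Dbp at 15.9 (1.89 to 5.69), Gcg at 0.103 (others 0), S100a8 at 16.2 (0.8496 to 3.504) and Socs3 at 269 (15.9 to 64.2).

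In liver at day 3, replicate 1 had Cyp7a1 at 146 (others 0.367 to 35.6), Car3 at 263 (1.38 to 64.1), Ces3a at 279 (34.1 to 80.8), Cyp21a1 at 68.4 (14.8 to 25.6), Gsta2 at 9.52 (2.99 to 4.86), Hsd3b5 at 5.93 (0.271 to 1.301), Inmt at 27.4 (0.504 to 7.199), Mt1 at 1249 (2992 to 3471), Myh2 at 0.584 (0.0867 to 0.155), Myh4 at 14.1 (0.871 to 4.07), Scd1 at 1815 (268 to 466), Slco1a1 at 42.9 (1.29 to 9.67) and Sult2a8 at 39.8 (2.02 to 9.11). Replicate 2 had Inhbb at 61.05 (30.3 to 34.1) and Stat3 at 348 (204 to 238).

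In liver at day 7, replicate 1 had Inhba at 12.4 (others 3.88 to 5.73). Replicate 2 had Cacna1b at 43.3 (3.07 to 13.6). Replicate 3 had Yap1 at 105 (60.6 to 68.2), Igfbp1 at 391 (27.98 to 109.9), Fgf21 at 50.6 (0.0943 to 1.12), Pdk4 at 127 (13.5 to 28.2) and Slco1a1 at 101.4 (2.44 to 19.9). Replicate 4 had Cyp2c54 at 352 (37.8 to 73.6), Cyp2e1 at 5169.7 (1268 to 1389), Ppara at 611 (170.0 to 199.7) and Sdha at 264 (164 to 191). Replicate 5 had Ccnd1 at 445 (237 to 250.1), Myh1 at 1.11 (0.0446 to 0.152), Myh2 at 0.423 (0 to 0.114), Myh4 at 20.3 (0.562 to 1.13), Ryr1 at 5.15 (0.134 to 0.602), Ttn at 163 (7.31 to 16.9) and muscle fibre markers at 83.4 (6.62 to 13.4).

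In quadriceps at day 1, replicate 1 had Foxo1 at 108 (others 378 to 448) and Oasl2 at 2.199 (0.442 to 0.907). Replicate 2 had a total of 15506197 counts (others 18812370 to 19865060). Replicate 3 had Myh2 at 2612 (174 to 602), Myh7 at 206 (1.34 to 28.6) and B3galt2 at 8.37 (0.911 to 1.83). Replicate 5 had Socs3 at 53.3 (3.36 to 7.497), Adrb3 at 1.34 (0.0651 to 0.213), Dio2 at 146 (3.84 to 10.2), Elovl6 at 6.03 (1.37 to 2.51), Hcar2 at 2.13 (0 to 0.213), Junb at 316 (23.2 to 58.7), Maff at 211 (10.1 to 47.8) and Tmem252 at 65.8 (4.05 to 19.3).

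In quadriceps at day 3, replicate 1 had Gbp7 at 22.8 (others 7.03 to 9.699), Gcg at 0.121 (others 0), Igfbp3 at 510.1 (50.5 to 179) and Tgfb2 at 24.4 (13.95 to 16.4). Replicate 3 had Hcar1 at 0.557 (0 to 0.146). Replicate 4 had Alb at 95.8 (0.483 to 19.2), Apoa2 at 1.703 (0.0439 to 0.455), Ces3a at 1.31 (0.0439 to 0.202), Gc at 6.23 (0.132 to 1.15) and hepatocyte markers at 226 (2.62 to 53.3). Replicate 5 had Casr at 2.28 (0.363 to 0.876), Col1a1 at 38.1 (4.24 to 5.97), Col6a1 at 19.9 (8.41 to 11.7), Dbp at 11.02 (2.14 to 3.896), Lcn2 at 389 (89.2 to 156), Mki67 at 5.49 (0.354 to 0.778), Ncl at 160.5 (252 to 288) and Psmb4 at 116 (207 to 227).

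In quadriceps at day 7, replicate 1 had Ins2 at 0.0434 (others 0). Replicate 2 had Myh7 at 500.4 (3.31 to 95.7), Myh3 at 84.6 (1.84 to 23.3), Sln at 25.6 (1.95 to 6.202) and Tnnt1 at 71.9 (1.01 to 20.6). Replicate 3 had Trim63 at 2285 (52.5 to 422), Fbxo30 at 167 (25.9 to 43.97), Cebpd at 458 (12.6 to 81.9), Pdk4 at 10236 (200.1 to 2273), Ddit4 at 225 (4.69 to 24.96), Alb at 54.3 (0.912 to 3.997), Doc2b at 67.9 (2.47 to 14.3), Fam65c at 1.79 (0.305 to 0.391), Hnf4a at 1.03 (0 to 0.04596), Igfbp1 at 0.759 (0 to 0.0459) and hepatocyte markers at 125 (4.12 to 8.698). Replicate 4 had Nnat at 8.92 (0 to 0.912) and Adipoq at 268 (0.566 to 54.4).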

How the results depend on the processing

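The adipocyte covariate, likelihood ratio test, selected day 1 libraries and removal of muscle genes were chosen after seeing the data. Of changes in named genes called with all libraries, 0 of 649 reversed with the compared groups alone, 0 of 703 by DESeq2, 0 of 703 with no filter, 0 of 654 with other size factors and 0 of 6114 when 1 library was left out, where 1053 lost their call. Of uncalled changes the direction turned in 2 of 363, 4 of 441, 1 of 444, 0 of 382 and 108 of 4164, and 100 of these 4164 became called. With other size factors the largest shift in the median of all genes was -0.03 (log2).

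DESeq2 called 575 genes in liver from day 3 to 7, 1804 and 292 in quadriceps at days 1 and 7, 1481 differing by tissue at day 7 and 1713 shared by the tissues (edgeR 1054, or 585 at 2-fold and more, where shared rises at day 3 turned from a deficit to an excess). The likelihood ratio test gave 462 for liver day 3 to 7 and 1609 and 150 in quadriceps. The compared groups alone gave 1307 and 7187 genes in liver at days 1 and 3, and 2259 and 2 in quadriceps at days 1 and 7. A block for replicate number gave 82 genes for liver day 3 to 7, and 208 and 1 in quadriceps at days 1 and 7, but libraries of 1 number did not pair (r over 0.1 in 5 of 24 liver and 3 of 24 quadriceps pairs). Liver and quadriceps libraries of 1 group and number had r over 0.1 in 11 of 18 pairs (median 0.124) and 9 were closest to their own number, a hint of shared animals from the data alone. With a term for each such pair the genes differing by tissue were 1420, 5602 and 897 at days 1, 3 and 7, while the overlap of the tissues has no such term. The muscle-rich day 1 livers gave 2003 genes against sham and 596 to day 3, and the islet-read day 1 quadriceps gave 0 (2955 unadjusted) and 1368. These settings keep fewer libraries, and for the others the cause was not tested.

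The adipocyte covariate left edgeR 0, 719 and 0 genes in quadriceps at days 1, 3 and 7 (1255 and 641 unadjusted at days 1 and 7). It reversed Rbp4 (0.62), Retn (0.56) and Cfd (0.56) at day 3. Reversed list medians were adipocyte markers (0.62, 0.56 and 0.26 at days 1, 3 and 7), cholesterol synthesis (0.091 and 0.33 at days 1 and 7), mitosis (0.31 at day 1), oxidative phosphorylation (-0.16 at day 7) and interferon response (0.21 at day 7). The covariate takes out fat-linked change by construction, and for the rest the cause was not tested. With an estimated correlation camera called 0 list tests in liver and 0 in quadriceps, and fry 60 and 29, against 65 of 114 and 55 of 93.

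Without 1 library, counts ran from 1797 to 5056, 2382 to 3584 and 782 to 3354 in liver at days 1, 3 and 7, 2312 to 4843 from day 1 to 3 and 17 to 626 from day 3 to 7. In quadriceps they ran from 0 to 1292, 4775 to 6924 and 0 to 51, then 2593 to 4283 and 3394 to 5920. The 0 came without any 1 sham (2373 to 2899 unadjusted at day 1, 997 to 1189 at day 7), and at day 7 also without its replicate 5 (1292 unadjusted). Genes differing by tissue ran from 825 to 2024, 4527 to 5738 and 371 to 1313, called named genes per tissue from 143 (quadriceps without sham replicate 2 or 3) to 434 and called lists from 49 to 67. Sham has 3 libraries and PHx 5, so the lone sham group weighs on every day. Islet reads split sham from days 3 and 7 in both tissues, so any batch behind them cannot be told from PHx. Depth sets a floor of 3 counts, 0.0382 CPM over the sham livers.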

Other observations

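Splits of the liver libraries were tested only after their counts were seen. Those of quadriceps and of the tissue difference, by number across tissues, were planned. Single clock genes changed in both tissues. In liver at day 1, 5 of 20 (list alone, 8) rose, among them Arntl (3.67 ± 0.66), and 6 fell, among them Usp2 (-2.97 ± 0.49), with no camera call (adjusted p = 0.314). At day 7 the list was called down, with 3 of 20 (adjusted over the list alone, 3) lower, such as Bhlhe41 (-2.93 ± 0.72) and Nr1d1 (-2.0 ± 0.62), and Arntl still up (2.27 ± 0.62; adjusted p = 0.01). In quadriceps at day 3, 8 of 20 (list alone, 9) rose and 4 fell, with Cry2 (2.79 ± 0.52) higher and Dbp (-4.52 ± 0.71) lower (adjusted p = 0.466). Hours of killing are not given, so the time of day is an open variable. For liver day 7, Arntl was 1.51 without day 7 replicate 3, and Nr1d1 was not called without any 1 sham or day 7 replicate 2, 3 or 5, nor Arntl without any 1 sham (edgeR, adjusted p 0.0537 to 0.101).

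Each gene count was set against splits of the same libraries, 56 per comparison with sham and 100 random ones between days, the real split included. Under 5% of splits had as many genes, unadjusted over comparisons. This held for liver days 1 (3841 genes, highest other 5848), 3 (3967, 0) and 7 (2658, 1636). It held for liver days 1 to 3 (3501, 759) and 3 to 7 (175, 106). The same held for quadriceps days 1 (720, 972) and 3 (6454, 4409), and for days 1 to 3 (3564, 2173) and 3 to 7 (4971, 4379). It held for tissue differences at days 1 (1430, 2392), 3 (5302, 1982) and 7 (905, 774). At day 1 in liver, quadriceps and between tissues 2 of 56 splits had as many, the other above the real count, so chance stays open. The others named had 1. The liver split above the real count set day 1 replicates 2, 4 and 5 against the rest. For quadriceps day 7, 3 of 56 splits gave 8 genes or more and chance cannot be excluded. Setting day 7 replicates 2, 3 and 5 apart gave 1910 against the real 8, which points to a structure within day 7.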
